A study of Silurus asotus with 15 samples.

How the data were processed

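RNA was extracted with Trizol, treated with DNase and enriched for poly(A) messenger RNA with a bead kit, and paired-end libraries were prepared, per the labels. The series holds 15 libraries, 1 for each of 15 tissues of adult fish, and each tissue was treated as a group of 1. The labels do not say how many fish were used.

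The authors' table gives FPKM (fragments per kilobase of gene model and per mapped fragments) for 25089 genes in 15 columns. Per the submitters' processing notes, StringTie 1.3.4d was used. The aligner, the genome build and any filter on genes are not given in the sources used here. The deposited FPKM columns sum to different totals, from 239905 to 738341, so they are not TPM. A deposited annotation table gives scaffold, start, end, exons and a protein name for 25122 loci on 2648 scaffolds, and 25064 of the 25089 genes were found in it by locus tag. Its transcript and coding spans are identical at all 25122 loci, so lengths are coding lengths without untranslated regions. Positions are printed as the annotation gives them, counted from 1, on a build whose name is not given in the sources used here. The annotation names proteins rather than gene symbols, so symbols in the text stand for genes matched by protein name, and names of paralogs are uncertain. In all, 189 genes were at 0 in every library and 3776 carried no protein name.

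No counts were given, and no count test was used. Low values were examined for steps: in each library the commonest value of FPKM times coding length in kilobases, among values under 1, was taken as the step of 1 fragment. Against the smallest step, it was at most 1.096 times as large in 11 libraries, 4.17 times in muscle, 5.75 times in skin and mandibular barbel and 6.31 times in maxillary barbel. These are estimates of relative depth from the values, and no interval was derived from them. A gene at exactly 0 is described as listed at 0, and no fold is given against it. With 1 library per tissue no spread could be estimated, so no p-value was computed and every call is a rule of size that describes these libraries.

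The rules, the gene lists and the alternatives were fixed before the data were examined. A gene was detected at an FPKM of at least 1. It was tissue-enriched when its highest library had an FPKM of at least 5 and log2(FPKM + 1), with a pseudocount of 1, was at least the log2 of 5 above the next highest library. It was group-enriched when the lowest member of a group had an FPKM of at least 5 and was that far above the highest library outside; 10 groups were fixed from anatomy. For 10 pairs of tissues, genes were counted whose log2(FPKM + 1) differed by at least 2, which is 4-fold, with the higher library at an FPKM of at least 5. Libraries were compared by Spearman correlation across all genes. The share of summed FPKM in the 10 and 100 highest genes was computed per library.

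There were 37 gene lists with 621 entries and 604 distinct symbols, of which 516 matched a protein name; where several rows matched, the row with the highest mean was used. The lists cover neurons and glia, pituitary hormones, ionocytes, haematopoiesis, interrenal steroidogenesis, chromaffin cells, nephron, cardiomyocytes, fast muscle, hepatocytes, exocrine pancreas, islets, lymphocytes, macrophages, thrombocytes, erythrocytes, oocytes, meiosis and spermatids, testicular somatic cells, germ line, keratinocytes, mucous cells, pigment cells, taste buds, mechanosensory cells, Schwann cells, cartilage, fibroblasts, endothelium, cell cycle, oxidative phosphorylation, complement and coagulation, antimicrobial effectors, xenobiotic metabolism, opsins, crystallins and housekeeping genes. For each list and library, the median over members of log2(FPKM + 1) minus the mean of the 15 libraries was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart at a percentile of 99 or more.

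Named genes followed a fixed rule. Per tissue these were the 3 named tissue-enriched genes with the highest FPKM and up to 5 tissue-enriched members of the lists expected there. Per pair they were the 5 named genes with the largest difference in each direction, and per group the 5 named genes with the highest FPKM in the lowest member. List members could be named where their list is described. Genes outside this rule are said to have been chosen after their values were seen.

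The alternatives were other pseudocounts and FPKM minimums, FPKM rescaled by median ratios over 5659 genes above 1 FPKM in all libraries, FPKM rescaled to a common sum in every library, as in TPM, a 10-fold rule, a tau index of at least 0.9 in place of the fold, each barbel left out, Pearson correlation, every row of a symbol, and list members at 1 FPKM or more in any library. Median-ratio factors ran from 0.517 in pancreas to 2.06 in ovary. The top-gene share without mitochondrially encoded and ribosomal RNA genes was not run, because 0 rows carried such a name. Leaving out the libraries labelled brain and gill, and setting each in the place of the other, were added after the data were seen, because their markers go against their labels.

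The tissue, pair, group and list rules were tested on simulated data, but the correlations, top-gene shares and quartile ratios were not. Libraries were drawn around each gene's median FPKM with a log2 scatter of 0.3, the same in every library, with no count noise or difference of depth. From the genes with a median FPKM of at least 2, 200 were raised by known folds, 50 per fold size. With 25089 genes, the tissue-enriched rule recovered 64% of the genes raised 8-fold and 100% of those raised 16-fold or 32-fold in 1 library, 0% of those raised 3-fold, and called 0 of 24889 unchanged genes. So small a scatter leaves almost no room for such calls, so that 0 is not a rate of false calls for the real libraries. Recovery of genes at lower FPKM was not tested. The pair rule recovered 92% at 8-fold and 10% at 3-fold in a simulated pair of libraries, and the group rule 22% at 8-fold and 100% at 16-fold in a simulated group of 2. Of 900 combinations of a random list and a simulated library, 0.778% reached percentile 99. So did 30 of 30 lists of genes with a median FPKM of at least 2, raised 2-fold in 1 library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.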

Results

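Poly(A) RNA from 15 tissues of adult Amur catfish (Silurus asotus), a bottom-living freshwater fish with sensory barbels around the mouth, was sequenced as paired-end libraries, with 1 library per tissue. The tissues were brain, pituitary, gill, heart, liver, pancreas, spleen, kidney, head kidney, ovary, testis, muscle, skin, maxillary barbel and mandibular barbel. The head kidney of a teleost holds blood-forming tissue together with the steroid-producing interrenal cells. The labels state no aim beyond a survey of tissues, and the comparisons below ask which genes set each tissue, or each group of related tissues, apart from the others. There were no replicates, so every value stands for 1 library and no difference has a replicate check. Expression was given as FPKM for 25089 genes, of which 21313 carried a protein name. No read counts were given. The summed FPKM ran from 239905 in skin to 738341 in pancreas. The commonest low value, multiplied by coding length in kilobases, lay between 0.0204 and 0.0224 in 11 libraries, and at 0.0851 in muscle, 0.117 in skin and mandibular barbel and 0.129 in maxillary barbel. If that step stands for 1 fragment, those 4 libraries were 4.17 (muscle) to 6.31 times (maxillary barbel) shallower than the deepest. This is an estimate from the values, not a stated depth. Values near 0 were therefore coarser in muscle, skin and barbels.

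Hormones, digestive enzymes, plasma proteins, egg coat proteins and contractile proteins were among the named genes found mainly in a single library. The highest such gene of its library was somatotropin in pituitary (133423 FPKM), cationic trypsin-3 in pancreas (81707.9 FPKM), apolipoprotein A-I in liver (38448.6 FPKM), creatine kinase M-type in muscle (12679.9 FPKM) and myoglobin in heart (11960.3 FPKM). By a rule of size, 2353 genes were tissue-enriched, meaning an FPKM of at least 5 in the highest library and a value at least 5-fold above the next library on the log2(FPKM + 1) scale. That scale understates the fold of low genes. The counts were 606 in the library labelled gill, 444 in ovary, 342 in liver, 257 in testis, 181 in muscle, 150 in the library labelled brain, 103 in heart, 90 in pituitary, 87 in pancreas, 42 in spleen, 27 in kidney, 21 in skin, 2 in maxillary barbel, 1 in head kidney and 0 in mandibular barbel. Their size and order depended on the scale and on the libraries compared. With FPKM rescaled by median ratios, ovary had 211, liver 462, muscle 266 and the library labelled brain 84. With each library rescaled to a common sum, the library labelled gill had 1163. Without the libraries labelled brain and gill, pituitary had 236. Genes detected at an FPKM of at least 1 ranged from 9823 in muscle to 15853 in testis. A few genes held much of the signal in some libraries: the 10 highest made up 56.2% of the summed FPKM in pancreas, 50.9% in pituitary, 40.2% in testis and 30.2% in liver, against 4.798% in the library labelled gill. In testis, 36.3% came from 1 unnamed gene of 150 coding bases, C0J50_24638, chosen after its values were seen (191378 FPKM, the highest value among all tissue-enriched genes). FPKM divides by length, so a gene this short takes a larger share of the summed FPKM than of the fragments.

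**Figure D1:**
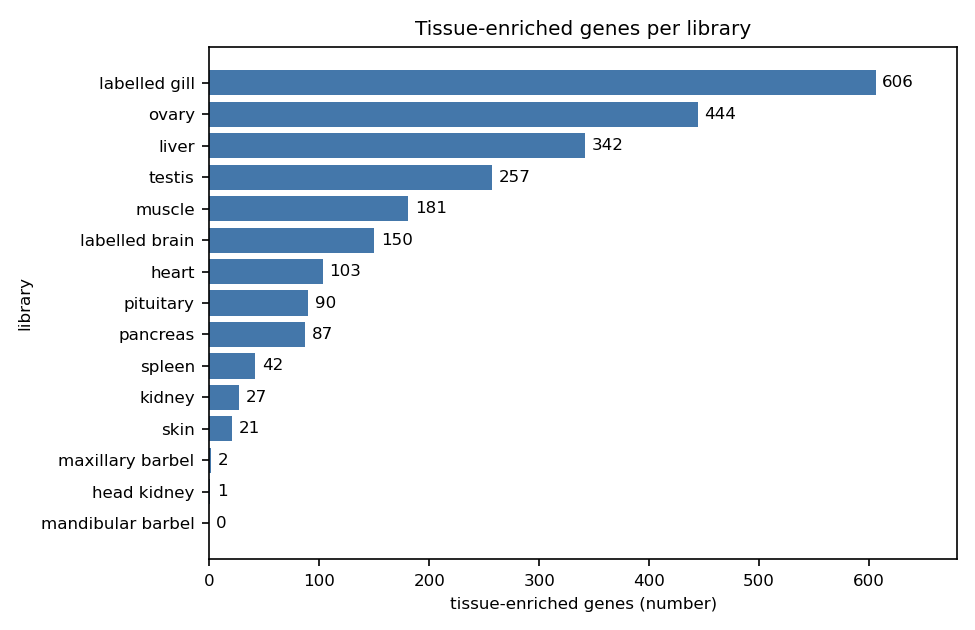
Number of tissue-enriched genes (x axis) in each of the 15 libraries (y axis), 1 library per tissue. The bars run from 0 in mandibular barbel to 606 in the library labelled gill.

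Markers of nerve tissue were found in the library labelled gill, and markers of gill epithelium in the library labelled brain. SNAP25, a protein of synaptic vesicle fusion (C0J50_21090, scaffold178232, 751521 to 761347, 7 coding exons), had 1658.7 FPKM in the library labelled gill and 0.0938 in the library labelled brain. The NMDA receptor subunit grin1 had 836.2 FPKM in the library labelled gill and was listed at 0 in the library labelled brain. Of the 20 members of the neuron and glia list, 18 were higher in the library labelled gill, where the list's median lay 5.95 above the mean of the 15 libraries on the log2 scale. Complexin-2 (734.1 against 0.0819 FPKM), the glial protein S100-B (675.5 against 0.173) and myelin basic protein (345.2 against 0.549) followed the same direction. Ependymin, a secreted glycoprotein of fish brain, led the genes enriched in the library labelled gill with 1897.5 FPKM, ahead of SNAP25 and aldolase C (887.3 FPKM). The Schwann cell and nerve list had its highest median there too (1.302, percentile 99.20). A list's percentile is that of its median among 10000 random lists of the same size and matched mean expression, as a description of these libraries.

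In the opposite direction, Rhcg, an ammonia channel of ionocytes (C0J50_07182, scaffold784, 48681 to 52187), had 232.2 FPKM in the library labelled brain and was listed at 0 in the library labelled gill. Rhbg (117.2 against 0.0380 FPKM), the sodium/proton exchanger NHE3 (114.6 against 0.0418), the ionocyte factor foxi3 (118.5 against 0.106) and gcm2 (96.2 against 0.0436) were likewise higher in the library labelled brain. Keratin 4 had 984.7 FPKM there and 0.124 in the library labelled gill, and 18 of 19 members of the keratinocyte and junction list shared that direction. So did 9 of 10 members of the mucous cell list, among them mucin-5AC with 726.4 FPKM in the library labelled brain and 0 in the library labelled gill. Claudin-4, a tight junction protein (C0J50_14498, scaffold178119, 1767450 to 1768088, 1 coding exon), led the genes enriched in the library labelled brain with 1359.7 FPKM, against 40.1 in the next library. Of the 17 matched ionocyte genes, 8 were higher in the library labelled brain and 9 in the library labelled gill, a tally that includes genes near 0. The electrogenic sodium bicarbonate cotransporter 1 was enriched in the library labelled gill (102.6 against 4.53 FPKM in the library labelled brain). The list's median stood apart in kidney (1.05, percentile 100) and in the library labelled brain (0.97, percentile 99.99), and not in the library labelled gill (-0.031, percentile 44.25). Because these markers go against the labels, both libraries are named by label only, and each direction drawn from them below is that of the library, not of the tissue.

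**Figure D2:**
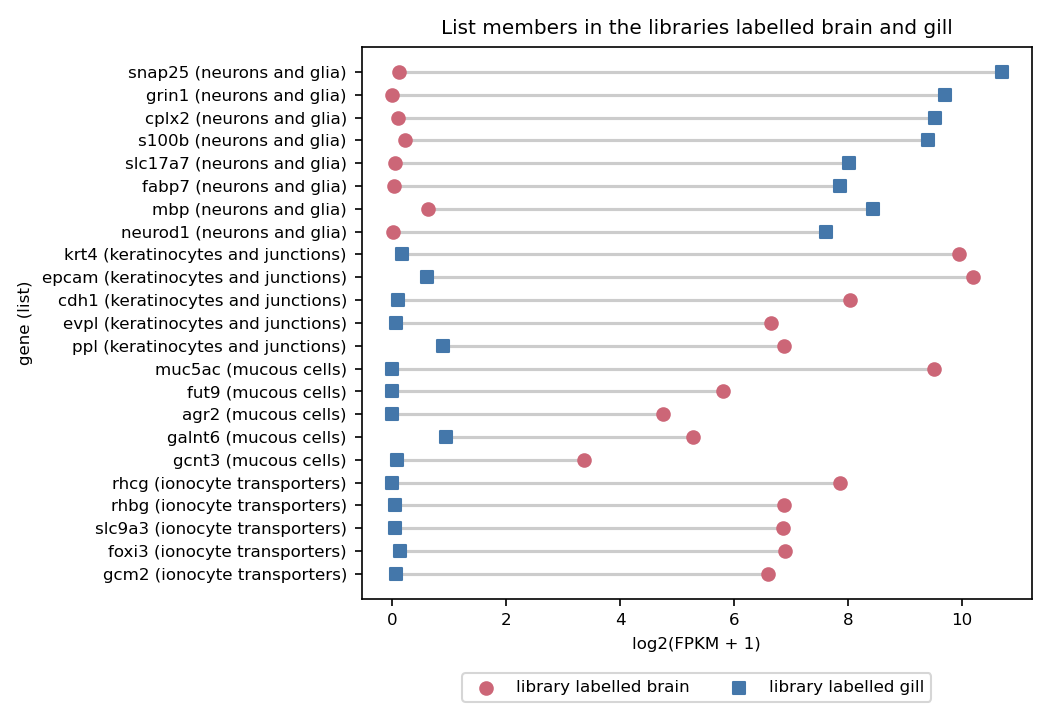
Expression as log2(FPKM + 1) (x axis) of list members in the libraries labelled brain (circles) and gill (squares), with each gene's list in brackets (y axis). Members were picked by direction. Those of the neuron and glia list have the largest excess in the library labelled gill. Keratinocyte, mucous cell and ionocyte members have the largest excess in the library labelled brain. Members going the other way, such as 9 of 17 ionocyte genes, are not shown. SNAP25 stands at 1658.7 FPKM in the library labelled gill and Rhcg at 232.2 FPKM in the library labelled brain, each with a value under 0.1 FPKM in the other library.

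The library labelled brain was compared with pituitary and the library labelled gill with skin, as the pairs implied by anatomy. Between the library labelled brain and pituitary, 2216 genes differed by at least 4-fold, 63.6% of them higher in the library labelled brain. Claudin-4 and keratin 4 led that side, and somatotropin (listed at 0 in the library labelled brain), prolactin and pro-opiomelanocortin led the pituitary side. With FPKM rescaled by median ratios, 43.9% were higher in the library labelled brain, so the side with more genes depended on the scale. Between the library labelled gill and skin, 5102 genes differed, 79.3% of them higher in the library labelled gill and 63.2% after rescaling. Ependymin led one side, and keratin 4 (0.124 against 2086.8 FPKM) and a type I cytokeratin (0.872 against 3213.2 FPKM) led the other. Pairing by the other label, chosen after the values were seen, gave 2111 genes between the library labelled gill and pituitary. Cerebellin-3 (717.5 FPKM) and the neural transcription factor ZIC1 (671.2 FPKM) were among the highest differences on the side of the library labelled gill. It gave 3811 between the library labelled brain and skin. The share higher in the library labelled gill than in pituitary was 74.6%, and 88.3% with each library rescaled to a common sum. The share higher in the library labelled brain than in skin was 88.4%, and 47.4% after median ratios.

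Hormone genes dominated the pituitary library. Somatotropin, the growth hormone (C0J50_19417, scaffold178209, 4921263 to 4923011, 4 coding exons), made up 26.3% of its summed FPKM. Prolactin reached 52715.6 FPKM, pro-opiomelanocortin, the precursor of corticotropin and melanocyte-stimulating hormone, 45721.5, the glycoprotein hormone alpha chain 5986.4 and the luteinizing hormone beta chain 3306.3. Of the 13 matched members of the pituitary list, 11 were tissue-enriched in pituitary, and the list's median was 7.71 above the mean of the libraries. Thyrotropin beta (385.2 FPKM), follitropin beta (330.03 FPKM) and the pituitary transcription factor Pou1f1 (192.5 FPKM) were among them. The neuron and glia list also stood apart in pituitary (1.24, percentile 100), and the chromaffin cell list had its highest median there (0.80, percentile 99.37) and a lower one in head kidney (0.56, percentile 99.97). Under the fixed group of brain and pituitary, 1 gene passed, a calcium/calmodulin-dependent protein kinase 1Db, with at least 10.4 FPKM in both libraries. The group of pituitary and the library labelled gill, added after the values were seen, gave 98 genes, led by midkine b (454.1 FPKM in the lower member), S100-B and the prohormone convertase inhibitor-like gene (165.7 FPKM).

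The barbels carried genes of taste cells over an epidermal profile shared with skin. Calretinin, a calcium-binding protein of taste cells (C0J50_20057, scaffold178217, 120408 to 128533), had 246.4 FPKM in maxillary and 260.3 FPKM in mandibular barbel against 1.87 in skin, the next library. The G protein subunit gng13a had 232.0 and 380.4 FPKM in the barbels and 3.98 in skin. The genes enriched in both barbels over all other libraries numbered 25, with 41 after median ratios and 53 without the libraries labelled brain and gill. Both genes headed the 18 of the 25 with a name, followed by a gene named vegetative cell wall protein gp1-like (158.4 FPKM in the lower barbel), phosphoserine aminotransferase (110.4) and C19orf12 homolog (107.1). The taste bud list had medians of 1.95 in mandibular and 1.70 in maxillary barbel, both at percentile 100, and 14 of its 20 matched members were highest in a barbel. Among them were gna14 (13.3 and 14.9 FPKM in maxillary and mandibular barbel), gnb3 (11.995 and 14.8), the channel subunit calhm3 (3.67 and 6.30) and the cation channel trpm5 (2.90 and 3.63), all under 1 FPKM in skin. The taste receptor subunit tas1r3 had 3.75 and 5.22 FPKM in the barbels and 12.4 in liver.

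Keratinocyte and junction genes stood apart in the library labelled brain (2.80), maxillary barbel (2.63), mandibular barbel (2.42) and skin (2.34), all at percentile 100. Keratin 4 had 2823.4, 2047.1 and 2086.8 FPKM in maxillary barbel, mandibular barbel and skin, and periplakin 133.3, 131.8 and 32.8 FPKM. Mucous cell genes stood apart in maxillary barbel (2.21), the library labelled brain (2.08) and mandibular barbel (1.46). With every gene of a matched name in place of the highest, the median in both barbels turned to -0.018. Mucin-5AC had 122.6 and 100.6 FPKM in the barbels and 2.05 in skin. Both barbels and skin shared 39 enriched genes, 100 with median ratios and 129 without the libraries labelled brain and gill. The 33 with a name were led by Rab11 family-interacting protein 1 (279.8 FPKM in the lowest member), histamine N-methyltransferase, an enzyme of histamine breakdown (256.1), SRR1-like protein (182.8), FAM133 (179.1) and a butyrophilin-like gene (158.8). With gill added to that group no gene passed; with the library labelled brain in its place, added after the values were seen, 56 did, led by keratin 4, a type I cytokeratin and keratin 97. In skin alone, ladderlectin, a lectin gene, led the named genes with 858.2 FPKM, followed by slow-type troponin C (208.9 FPKM) and rapunzel 5 (173.6 FPKM).

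The 2 barbels differed little: 52 of 5495 compared genes, or 0.946%, differed by at least 4-fold, 31 of them higher in maxillary barbel. The count was 82 with median ratios and 195 after rescaling to a common sum. This pair of near-identical organs is a yardstick for the other pairs, not a replicate pair. Both barbel libraries were also estimated to be shallow, so the yardstick is not like for like with pairs of deeper libraries. Among the named genes with the largest differences, interferon-induced protein 44 had 18.8 FPKM in maxillary barbel and was listed at 0 in mandibular barbel. Guanylate-binding protein 1 had 90.4 and 6.40 FPKM, and a major histocompatibility class II gene 16.1 and 0.0121. On the mandibular side stood a zinc finger gene named XlCGF28.1-like (C0J50_04847, 1401.5 against 0.0673 FPKM), 2 genes named TBX3, a patterning transcription factor (12.9 against 0.525 FPKM, and 5.15 against 0), and 2 immunoglobulin lambda light chain genes (11.6 against 0.454 FPKM, and 29.6 against 3.75). The second TBX3 model and both light chain models begin near the start of separate scaffolds, so these may not all be separate genes. Another gene named XlCGF28.1-like, C0J50_15525, had 94.3 FPKM in maxillary barbel, 59.9 in mandibular barbel and 258.6 in skin. With the other barbel left out of the comparison, 33 genes were enriched in maxillary and 35 in mandibular barbel, in place of 2 and 0. Skin differed from maxillary barbel in 349 genes and from mandibular barbel in 364. Slow-type troponin C had the largest difference of the named genes on the skin side of both pairs. Regulatory myosin light chain 10 (155.7 FPKM) and cardiac-type troponin T2d (161.0 FPKM) were among the 5 largest in both, and a rhamnose-binding lectin gene (110.4 against 0.335 FPKM) was so against mandibular barbel. On the barbel side, the vegetative cell wall protein gp1-like gene had the largest difference of the named genes in the pair with maxillary barbel, and the XlCGF28.1-like gene C0J50_04847 in the pair with mandibular barbel. Calretinin and gng13a were among the 5 largest in both.

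Kidney and head kidney both carried a strong profile of blood formation and had the highest similarity of all pairs of libraries (Spearman correlation 0.955). Nephrosin, a protease of granulocytes (C0J50_21323, scaffold178239, 1071633 to 1074651), had 3322.8 FPKM in head kidney and 2729.3 in kidney, and a myeloid peroxidase named eosinophil peroxidase had 1826.9 and 1506.8. These headed the 5 genes enriched in both, a count of 14 with a pseudocount of 0.1, 3 with median ratios and 8 without the libraries labelled brain and gill. The haematopoiesis and myeloid list had medians of 3.24 in head kidney and 3.11 in kidney, followed by spleen (1.87), the library labelled brain (1.67) and heart (1.64). The erythrocyte list gave 2.62 in head kidney, 2.57 in kidney and 1.39 in heart, and alpha globin was the highest gene of the kidney library with 11440 FPKM. The thrombocyte list gave 2.24 in kidney, 2.16 in head kidney, 1.88 in heart and 1.44 in spleen. Between kidney and head kidney, 127 genes differed, 118 of them higher in kidney. Among the 5 largest differences of named genes were sulfate anion transporter 1 (55.1 against 0.0115 FPKM), inositol oxygenase (93.7 against 0.772), cadherin-17 (47.8 against 0.00713) and solute carrier 13A1, a sulfate transporter (43.7 against 0). The nephron list stood apart in kidney only (1.11, percentile 100), with 10 of 20 members highest there. Slc12a1, the sodium-potassium-chloride transporter of the distal nephron, had 25.7 FPKM, hepatocyte nuclear factor 1-beta 23.4, and the organic anion transporter slc22a6 16.7.

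The 5 named genes with the largest differences on the head kidney side included 3 of steroid synthesis: the cholesterol transporter StAR (76.9 against 0.249 FPKM in kidney), 3-beta-hydroxysteroid dehydrogenase (22.7 against 0.370) and steroid 21-hydroxylase (11.98 against 0.0344). The others were apolipoprotein A-I (13.9 against 0.330) and apolipoprotein Eb (29.5 against 2.06). Liver-enriched genes at 1000 FPKM or more had a median of 1 part in 2703 of their liver FPKM in head kidney. The hydroxylase, which acts in cortisol synthesis, was the only gene enriched in head kidney. The interrenal list had medians of 2.93 in testis and 2.08 in head kidney, both at percentile 100. Head kidney differed from spleen in 964 genes, with 33.8% higher in head kidney and 19.95% after median ratios. Argininosuccinate synthase (177.3 against 5.37 FPKM) and carbamoyl-phosphate synthase (39.4 against 1.17), enzymes of the urea cycle, were higher in head kidney. In the opposite direction, the XlCGF28.1-like zinc finger gene C0J50_04847 (402.9 FPKM), a microfibril-associated glycoprotein 4-like gene (213.8) and an aquaporin 8a copy (171.0) were higher in spleen.

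The macrophage and lymphocyte lists had their highest medians in spleen. That of the macrophage list was 3.23, but with every gene of a matched name in place of the highest the list fell to percentile 85.99 in spleen. Among its members were C1q subunit C at 1087.2 FPKM, the scavenger receptor MARCO at 350.8 and heme oxygenase 1 at 207.3. That list also stood apart in the library labelled brain (1.64), head kidney (1.45), kidney (1.43), testis (0.97) and heart (0.96). The lymphocyte list gave 2.16 in spleen, 1.02 in head kidney, 0.95 in the library labelled brain and 0.74 in kidney. Tlx1, a transcription factor needed for spleen formation (C0J50_24898, scaffold178316, 347941 to 350873), had 43.1 FPKM in spleen and 0.393 in the next library. A membrane-spanning 4-domain gene (1201.2 FPKM), a C1q-like gene (784.1) and an intelectin-like gene (429.8) led the 42 genes enriched in spleen. The antimicrobial list stood apart only in spleen (1.52, percentile 99.96), where lysozyme g-like 1 had 412.3 FPKM. Kidney, head kidney and spleen shared 4 enriched genes (7 with a pseudocount of 0.1), while head kidney and spleen alone shared none. The 4 were 2 genes named GPR182, a G-protein coupled receptor, and 2 named as an immunoglobulin kappa variable segment. Both GPR182 models and 1 kappa model begin near the start of separate scaffolds, so 4 may overstate the number of genes.

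Heart and muscle were set apart by different members of the same families of contractile proteins, such as myosin heavy chains. Cardiac-type troponin C (C0J50_24735, scaffold178304, 80920 to 83532, 5 coding exons) had 5825.8 FPKM in heart, cardiac myosin light chain-1 4320.3, a myosin heavy chain 7-like gene 3539.5 and natriuretic peptide A 2993.2, and all 4 were listed at 0 in muscle. Fast skeletal myosin heavy chain (C0J50_12356, scaffold43030, 107 to 776) had 11652.4 FPKM in muscle and was listed at 0 in heart. The cardiomyocyte list had a median of 5.60 in heart and the fast muscle list 7.98 in muscle, where 16 of 19 members were enriched. The fast muscle list also stood apart in skin (1.15, percentile 100). It passed narrowly in mandibular (0.11) and maxillary barbel (0.0059), at percentiles of 99.75 and 99.42 that became 98.94 and 98.22 after median ratios. In skin, muscle-enriched genes at 1000 FPKM or more had a median of 1 part in 260 of their muscle FPKM. The upper quartile of that ratio was 4.02 times the lower. The median was 1 part in 432 in mandibular and 794 in maxillary barbel. Whether RNA or reads of the muscle sample account for the fast muscle genes there was not tested. In total 2626 genes differed, 84.3% of them higher in heart and 63.2% after median ratios. Both tissues shared 72 enriched genes, led by aldolase A (2292.7 FPKM in the lower member), creatine kinase M-type (1189.1), muscle creatine kinase a (1087.1), sarcalumenin (392.7) and desmin (381.1). The oxidative phosphorylation list stood apart in muscle and heart (1.22 each, percentile 100) and in the library labelled brain (1.13, percentile 99.55).

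Plasma proteins marked the liver and digestive proenzymes the pancreas. Apolipoprotein A-I (C0J50_14460, scaffold178119, 759865 to 760855, 3 coding exons) had 38448.6 FPKM in liver and 108.2 in the next library, and fibrinogen gamma, beta and alpha chains had 16650.1, 13206.1 and 9695.2 FPKM. Of the 27 matched hepatocyte genes, 23 were enriched in liver (median 8.84), and of the 24 complement and coagulation genes 20 were (median 8.03). The complement list stood apart in pancreas (0.96) and spleen (0.83) as well. Of its members, C7 (3583.5 FPKM) and C6 (540.4 FPKM) were highest in spleen. The hepatocyte list stood apart in spleen (0.999, percentile 100), where none of its members was highest. In spleen, liver-enriched genes at 1000 FPKM or more had a median of 1 part in 374 of their liver FPKM. In pancreas it reached percentile 99.98 with a median of -0.30, which turned to 0.18 after median ratios. The xenobiotic metabolism list stood apart in liver (1.52, percentile 99.99), with cytochrome P450 1A1 at 152.9 FPKM. In pancreas, trypsinogen had 65788 FPKM, the zymogen granule protein syncollin 63123.6, carboxypeptidase B 23908.9 and an elastase 3-like gene 13113.5. The exocrine list had a median of 10.95 in pancreas. It also passed in pituitary (0.63, percentile 99.25, and 98.84 after median ratios). The islet list had medians of 2.14 in pancreas and 2.11 in pituitary. Somatostatin 2 (4133 FPKM), insulin (1066.5 FPKM) and glucagon (661.6 FPKM) were enriched in pancreas, and the prohormone convertase pcsk2 (822.3 FPKM) in pituitary. Liver and pancreas differed in 1210 genes, 73.8% of them higher in liver, and 87.6% when each library was rescaled to a common sum. They shared 27 enriched genes (68 with median ratios), led by a complement factor H-like gene (1644.3 FPKM in the lower member), a gene named SVEP1 (718.1), cysteine dioxygenase (487.7) and S-adenosylmethionine synthase (195.7).

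Egg coat proteins and maternal factors marked the ovary, and steroid, Sertoli cell and sperm genes the testis. Zona pellucida glycoprotein 2 (C0J50_10470, scaffold10073, 405 to 2166, 8 coding exons) had 8675.5 FPKM in ovary, zona pellucida protein 4 7986.6, and BTG4, a factor of maternal messenger decay, 1019.0. The oocyte and granulosa list had a median of 7.09 in ovary, with 14 of 16 members enriched, among them bucky ball (528.9 FPKM), which organises the Balbiani body of fish oocytes, and zygote arrest 1 (391.0). Semaphorin-4E (2647.8 FPKM), clusterin (1213.1) and tubulin beta 2c (303.3) led the named genes enriched in testis. The testicular somatic list had a median of 4.58 in testis, where gonadal somatic cell derived factor had 190.3 FPKM and the sex-determination factor Dmrt1 59.0. The meiosis and spermatid list gave 2.52, with synaptonemal complex protein 3 at 61.4 FPKM and outer dense fiber protein 3-B at 59.7. The steroid 17-alpha-hydroxylase cyp17a1 had 173.9 FPKM in testis. The germ line list stood apart in ovary (3.91) and testis (3.67). The germ cell helicase DDX4, at 162.2 and 164.3 FPKM, led the 48 genes enriched in both gonads, and piwi-like protein 1 had 128.7 FPKM in testis against 20.5 in ovary. The gonads differed in 3399 genes, 39.3% of them higher in ovary and 30.5% after median ratios.

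The cell cycle list had medians of 3.14 in ovary, 2.64 in head kidney, 2.40 in kidney, 1.3002 in testis and 0.19 in mandibular barbel. Cyclins B2 and B1 had 299.1 and 263.3 FPKM in ovary, and the proliferation marker Ki-67 was highest in head kidney (56.3 FPKM). Endothelial genes stood apart in heart (2.11) and spleen (1.89), with von Willebrand factor at 105.5 FPKM in heart. Fibroblast and bone matrix genes did so in testis (1.67), heart (1.36), spleen (1.09), liver (0.39) and muscle (0.33), and in neither skin nor barbels. The Schwann cell list passed in muscle as well (0.36, percentile 99.94). Cartilage genes passed in pancreas alone, with a median of -0.072 and 9 of 15 matched members at 1 FPKM or more in any library, and not after median ratios (percentile 97.67). The pigment cell, mechanosensory, opsin, crystallin and housekeeping lists stood apart in no library. Only 5 of 12 matched pigment genes reached 1 FPKM anywhere. Over the 37 lists and 15 libraries, 81 of 555 combinations reached percentile 99, against 5.55 expected from random lists. Most lists were chosen as markers of cell types in these tissues and some share members, so an excess was built in and is not a test. Some of the 81 had a median below 0.

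**Figure D3:**
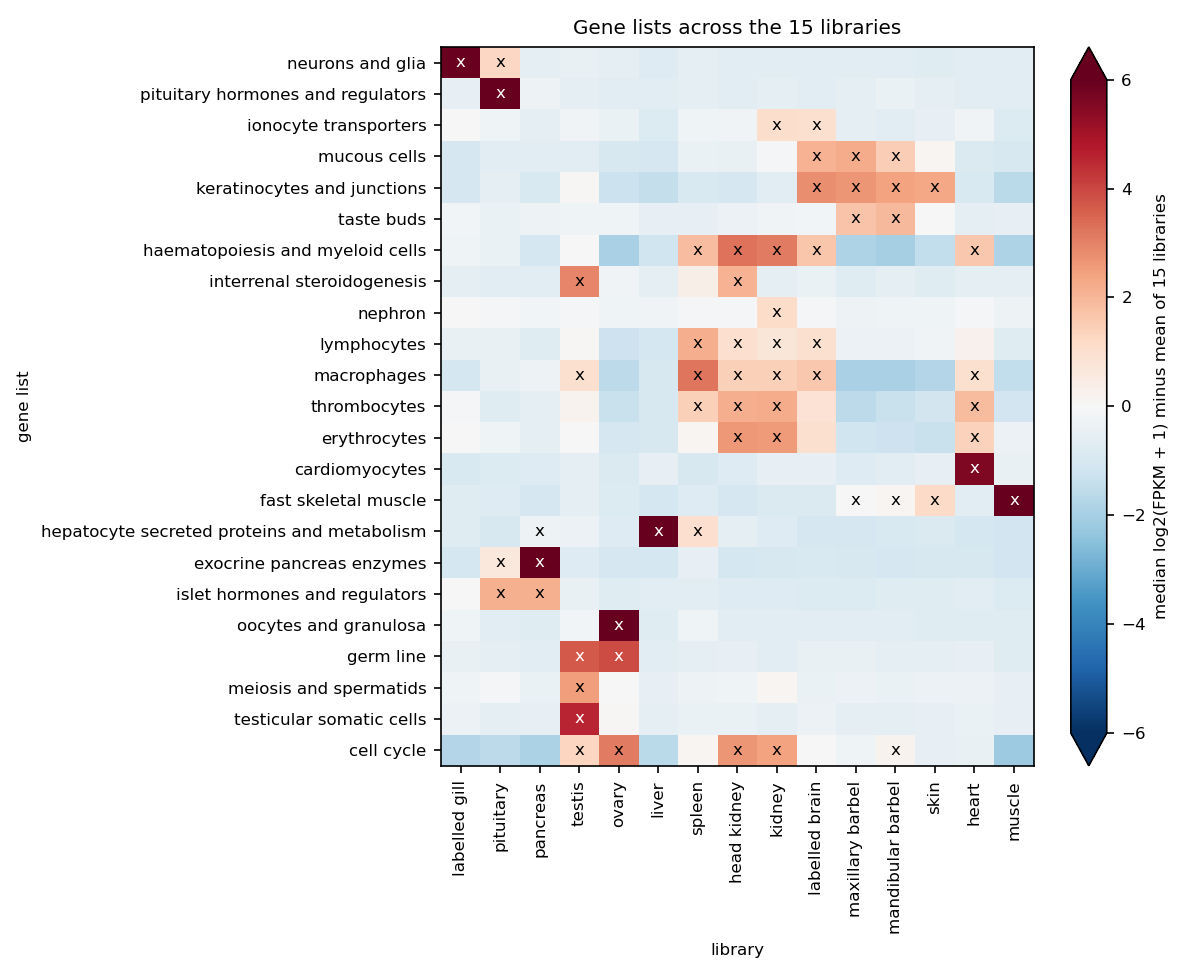
Median over list members of log2(FPKM + 1) minus the mean of the 15 libraries (colour, limited to 6 on either side) for 23 gene lists (rows) in each library (columns); crosses mark percentiles of 99 or more. The neuron and glia list is highest in the library labelled gill (5.95), and the keratinocyte list in the library labelled brain (2.80).

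By Spearman correlation across genes, which are not independent replicates, the closest pairs after the kidneys were both barbels (0.935), head kidney and spleen (0.917), kidney and spleen (0.893) and skin with maxillary barbel (0.892). The library labelled brain was closest to kidney (0.868). The library labelled gill was closest to pituitary (0.7998) and had the lowest correlation of all 105 pairs with skin (0.532). Ovary was closest to testis (0.797), and muscle to heart (0.813). Rescaling by median ratios moved the median log2 difference of all compared genes from 1.05 to 0.055 between heart and muscle, from 1.38 to 0.48 between the library labelled gill and skin, from 0.68 to -0.0090 between the library labelled brain and pituitary, from 0.33 to 0.071 between ovary and testis, from 0.18 to -0.11 between head kidney and spleen, and from 1.44 to -0.062 between the library labelled brain and skin. It moved that of skin from -0.015 to 0.15 against maxillary and from -0.10 to 0.15 against mandibular barbel. Rescaling to a common sum moved it from 0.20 to 1.03 between liver and pancreas and from 1.44 to 0.65 between the library labelled brain and skin. After that rescaling the number of differing genes was over 1.5 times as large in every fixed pair except ovary and testis. Counts of higher and lower genes in these pairs are therefore relative to the FPKM as deposited.

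**Figure D4:**
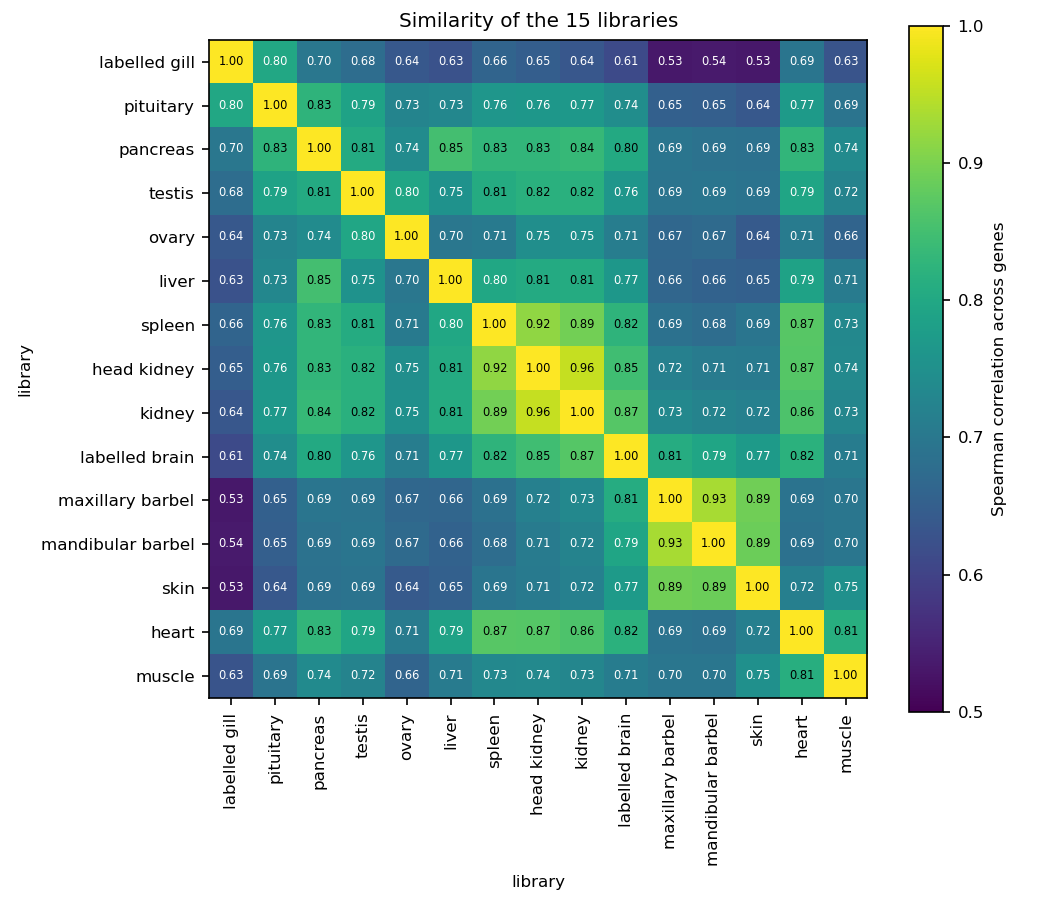
Spearman correlation across 25089 genes (colour and printed value) between each pair of the 15 libraries (rows and columns). Kidney and head kidney have the highest value (0.955), and the library labelled gill and skin the lowest (0.532).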

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

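Leaving out the libraries labelled brain and gill, and using the library of the other label, were alternatives chosen after the data were seen; all others were fixed before. Of 442 values under an alternative, 373 kept their direction and side of the threshold or stayed within 1.5 times the main count. No paired analysis was possible because each tissue has 1 library. The share of signal in top genes has no alternative value, since 0 rows were mitochondrially encoded or ribosomal RNA. Where a changed value follows from a stricter or looser rule, or from fewer libraries, that is its construction; otherwise the cause was not tested.

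The median number of genes detected was 12861, and 7687 at a minimum of 5 FPKM. Tissue-enriched genes fell from 2353 to 1186 at 10-fold, with counts of 65 in the library labelled brain, 255 in the library labelled gill, 59 in heart, 11 in kidney, 185 in ovary, 46 in pituitary, 8 in spleen, 126 in testis, 0 in maxillary barbel, 108 in muscle and 8 in skin. At an FPKM of at least 20 they were 379 in the library labelled gill, 0 in head kidney, 7 in kidney, 54 in pituitary, 141 in testis and 1 in maxillary barbel. Median ratios gave 84 in the library labelled brain, 15 in kidney, 211 in ovary, 4 in maxillary barbel, 1 in mandibular barbel and 39 in skin. Rescaling to a common sum gave 1163 in the library labelled gill, 2 in head kidney, 4 in maxillary barbel, 1 in mandibular barbel and 48 in skin. A tau of at least 0.9 gave 2 in head kidney, 245 in ovary, 19 in spleen, 6 in maxillary barbel and 17 in mandibular barbel. A pseudocount of 0.1 gave 73 in spleen and 2 in mandibular barbel. Without the other barbel, 33 genes were enriched in maxillary and 35 in mandibular barbel. Without the libraries labelled brain and gill, 236 were enriched in pituitary, including all 90 of the main count.

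Genes enriched in both barbels were 41 with median ratios and 53 without the libraries labelled brain and gill, against 25. Those of both barbels and skin were 60 with a pseudocount of 0.1, 100 with median ratios and 129 without those libraries, against 39. Kidney and head kidney gave 14 with a pseudocount of 0.1, 3 with median ratios and 8 without those libraries, against 5. Kidney, head kidney and spleen gave 7 with a pseudocount of 0.1, and liver and pancreas 68 with median ratios. With the library of the other label, the group of both barbels, skin and gill gave 56 and that of brain and pituitary 98.

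The barbels differed in 82 genes with a pseudocount of 0.1, and also in 82 with median ratios. Rescaling to a common sum, as in TPM, raises FPKM against a fixed minimum and pseudocount, and gave 195 for the barbels, 267 for kidney and head kidney, 1497 for head kidney and spleen, 3947 for heart and muscle, 3747 for the library labelled brain and pituitary, 921 and 908 for skin against maxillary and mandibular barbel, 7704 for the library labelled gill and skin, and 2041 for liver and pancreas.

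With every row of a symbol, the macrophage list fell to percentile 85.99 in spleen. The mucous list then had a median of -0.018 in both barbels and skin, below 0, at percentiles of 99.89 in maxillary barbel, 99.67 in mandibular barbel and 99.38 in skin. It also passed in skin with a pseudocount of 0.1 (99.69) and without the libraries labelled brain and gill (99.58). Closest libraries were as reported in 13 of 15 cases with Pearson correlation and in 14 of 15 with genes at 1 FPKM or more. Coarser low values in muscle, skin and barbels limit what can be said of genes near 0 there.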

Other observations

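The tests of the labels brain and gill, and the tests on pancreas genes at 1000 FPKM or more, were chosen after the result was seen; those on pancreas genes of lower level and on slow muscle genes were set before their values were seen. The genes of the next paragraph were chosen after their values were seen.

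Yolk protein genes were expressed in the liver library: 7 genes named vitellogenin had 13.4 to 70.2 FPKM in liver, and each was under 1 FPKM in the other 14 libraries. Of these, 4 lie together on scaffold249, between 1125180 and 1655531. The others are short models of 213, 342 and 432 coding bases on other scaffolds, so 7 may overstate the number of separate genes. Carbamoyl-phosphate synthase had 39.4 FPKM in head kidney, 35.1 in kidney and 27.6 in maxillary barbel, against 2.70 in liver. Inducible nitric oxide synthase had 25.5 FPKM in maxillary and 21.6 in mandibular barbel and was listed at 0 in liver. The XlCGF28.1-like zinc finger gene C0J50_04847, a single coding exon of 2403 bases on scaffold360 from 552774 to 555176, had 1401.5 FPKM in mandibular barbel, 402.9 in spleen, 353.3 in the library labelled brain and 326.2 in the library labelled gill, and at most 0.264 FPKM in the other 11 libraries. The gene C0J50_15525 of the same name was highest in skin (258.6 FPKM), with 94.3 in maxillary and 59.9 in mandibular barbel. An unnamed gene of 150 coding bases, C0J50_24638 on scaffold178299, held 36.3% of the summed FPKM of the testis library (191378 FPKM), a share that its short length raises. Another unnamed gene, C0J50_17775, had 3879.7 and 4784.5 FPKM in maxillary and mandibular barbel and 967.7 in skin. A further one, C0J50_23556, was the highest gene of heart with 18459.8 FPKM.

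The libraries labelled brain and gill may have exchanged labels. Of the 20 neuron and glia genes, 18 were higher in the library labelled gill, and of 29 keratinocyte and mucous cell genes, 27 were higher in the library labelled brain, so both libraries are out of place. Brain RNA mixed into a true gill library would leave epithelial genes near their level in other epithelia. Over the 19 such genes at 5 FPKM or more in skin and both barbels, the library labelled gill held a median of 0.0264 of the lowest of those levels, and the library labelled brain 2.58. The value of 2.58 argues against correct labels, even with little nerve in the brain sample, since a brain sample would hold these genes below skin and barbels; it replaces a test on the neuron and glia median in that library (-0.65), which could not have excluded them. Over all 29 epithelial genes the median in the library labelled gill was -0.996, just short of a bound of 1 below the mean that was tried first, and the tables cannot say at which step an exchange would have happened.

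Digestive enzymes in the pituitary library may be RNA or reads of the pancreas sample. For the 32 pancreas-enriched genes at 1000 FPKM or more, the pituitary held a median of 1 part in 1781 of the pancreas FPKM, and the upper quartile of that ratio was only 1.11 times the lower. On 28 pancreas-enriched genes at 100 to 1000 FPKM, the median ratio was 1.502 times as high, at the edge of the 1.5 set beforehand, and their quartile ratio of 5.65 is far from a constant ratio, so for these genes the question stays open. For the 32 genes, the quartile ratio was 0.0577 of its median over 6 other libraries. That comparison cannot decide on expression by the pituitary itself. Most of those libraries held the genes near 0, such as 1 part in 92581 in the library labelled gill and 580416 in ovary. Ratios of values near 0 scatter widely whatever their source. In spleen, at 1 part in 16408, the quartile ratio was 2.95. There were 70 source and recipient combinations, from 5 source libraries, with pituitary not among these sources. Of the 70, 38 had a lower quartile above 0 and so a quartile ratio, which was under 1.5 in 6. Besides pancreas genes in pituitary, the 6 included heart genes in kidney (1 part in 2856) and in the library labelled brain (1693). The rest were ovary genes in the library labelled gill (1680) and in spleen (1631), and liver genes in spleen (1 part in 374). The last bears on the hepatocyte and complement lists in spleen. In the reverse direction, pancreas was the next library for somatotropin (12.8 FPKM, against 133423 in pituitary) and prolactin (4.91, against 52715.6). For pro-opiomelanocortin it was the library labelled gill (11.1). Pituitary genes in pancreas were not examined as a set.

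Slow muscle fibres in the skin sample are a candidate source of the slow-type troponin C and myosin light chain 10 found there. Of 8 slow muscle genes that had not been named from the values, 5 were at 5 FPKM or more in skin and above both barbels. Slow myosin heavy chain 3 led them (54.9 FPKM, against 1.60 in muscle). A tropomyosin alpha-3 gene (36.9, against 5.33) and slow troponin I c (31.3, against 0.0938) followed. A second gene named slow myosin heavy chain 3, next to the first on scaffold94, was among the 5 at only 5.24 FPKM. So 5 may overstate the number of separate genes. The tropomyosin alpha-3 gene marks slow fibres less well. It had 14.8 and 10.6 FPKM in maxillary and mandibular barbel, where slow myosin heavy chain 3 had 0.173 and 0.340. A second tropomyosin alpha-3 gene among the 8 was lower in skin (6.39 FPKM) than in maxillary (16.4) and mandibular barbel (10.9). For the slow muscle genes, RNA or reads of the muscle sample are argued against, while fast muscle genes in skin were not covered. The median of those 8 genes in skin was 1.69 above that in muscle on the log2 scale, with 7 of 8 higher in skin. Among the 7, slow troponin I 1b (0.986 FPKM in skin, against 0 in muscle) and slow troponin T (3.05, against 1.27) were low. The exception was slow-type myosin-binding protein C, with 18.9 FPKM in skin and 40.1 in muscle. Heart also expresses some of these genes, such as the first tropomyosin alpha-3 gene at 61.8 FPKM, and expression by skin cells themselves was not tested.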
